A study of Homo sapiens with 6 samples.

How the data were processed

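Total RNA, with 1 ug per library, was made into TruSeq RNA libraries from cells labelled MCF-7 harvested 48 h after siRNA transfection, per the labels' protocols. The 6 libraries form a control siRNA group and a VASP siRNA group of 3 each, taken from the siRNA label of each sample and the number in its title. The siRNA sequences are not given in the sources used here, nor is the strand setting or the way reads were assigned to overlapping genes.

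The authors deposited a single gene-level table in FPKM, with Ensembl identifiers, symbols, biotypes and positions. The submitters' processing notes name bcl2fastq 2.18, HISAT2 2.0.4 and Cufflinks 2.2.1, and the build hg18. The positions in the table go against that build. Of 31542 identifiers shared with GENCODE release 29 on GRCh38, 96.4% had the same chromosome, start, end and strand and 94.6% the same symbol, while 148 identifiers had no match. Coordinates are therefore given as in the table and named GRCh38. FPKM divides fragments by gene length and library size, so a few abundant transcripts can shift all other values. Mitochondrially encoded genes took 31.9% to 34.3% of the summed FPKM.

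Exonic lengths from GENCODE 29 were used to recover depth from the steps between low FPKM values of genes with a single transcript. Of 62728 values of up to 20 reads, 97.2% came within 0.1 of a whole read, where 20% would by chance. Recovered depth was 16206096, 16144260 and 16132973 fragments for control siRNA replicates 1 to 3 and 16177174, 17145292 and 17435085 for VASP siRNA replicates 1 to 3. At most 0.086% of the genes with a mean of at least 1 FPKM had identical FPKM in any of the 15 pairs of libraries, so all 6 were counted separately. A level of 0 allows up to 3 reads, and such floors cover counting error only.

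The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on log2(FPKM + 1), VASP siRNA minus control siRNA, over 11633 genes with a mean of at least 1 FPKM. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Fold changes on this scale understate the change of genes with low FPKM. VASP was also tested by a two-sided exact permutation test over 20 arrangements. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists with at least 5 tested members out of 33. The lists, the tests of the comparison, the naming rule and the alternatives were set before the data were examined, except for 4 alternatives and for some tests on the standing-apart libraries and marker genes. The rule named VASP, ENAH and EVL, up to 12 genes per direction past the threshold, and list members past it, up to 3 per direction. Since no gene passed, the 10 smallest unadjusted p are given as values. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

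The procedure was tested on simulated data for the VASP siRNA comparison, with reads drawn for 11457 genes from the observed means, depth and dispersion. Changes were given only to genes with a mean of at least 100 reads. It recovered 17 of 67 genes changed 1.5-fold (25.4%), 59 of 67 changed 2-fold (88.1%) and 65 of 66 changed 4-fold (98.5%), and called a list shifted by 0.5 on the log2 scale. With no change, 3 genes and 0 lists were called. Genes were drawn independently of each other, so the simulation cannot show how camera behaves for lists of correlated genes. In the data the estimated correlation was 0.84 in the ribosomal list. Recovery at fewer reads was not simulated, and the simulated libraries hold no departure of a whole library from the rest. Each gene took the dispersion of the trend at its level, and all changes were made in the same run. The recovery rates may therefore overstate the power for a lone changed gene in the data.

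Alternatives covered pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, rescaling to equal sums, median-of-ratios scaling and quantile normalization. They also covered no trend, robust variances, library quality weights, a replicate block, the highest row per symbol, each library left out, other thresholds and other list tests. Count-based tests planned for a table of counts were not run, since the table holds FPKM.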

Results

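RNA sequencing was carried out on cells labelled MCF-7, an established human breast cancer line widely used as a luminal, estrogen receptor-positive model. The cells received an siRNA against VASP or a negative control siRNA and were collected 48 h after transfection, with 3 libraries in each group. VASP encodes vasodilator-stimulated phosphoprotein, an actin-binding protein of the Ena/VASP family that promotes filament elongation. The series asks how gene expression differs once VASP is knocked down. The deposited table gave FPKM for 31690 genes, and the steps between its low values place the depth at 16132973 to 17435085 fragments per library. A single read in a gene with 1 kb of exons was worth 0.0574 to 0.062 FPKM. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

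VASP (ENSG00000125753, chromosome 19, 45506579 to 45526983, plus strand in GRCh38) was lower in every library of the VASP siRNA group than in every control library. Its level was 21.5 ± 0.42 FPKM (SD, n = 3) with control siRNA and 15.1 ± 0.51 FPKM (SD, n = 3) with VASP siRNA, a ratio of 0.701. The control libraries held 21.6, 21.8 and 21.02 FPKM and the VASP siRNA libraries 15.6, 14.9 and 14.7 FPKM, from 911 to 1269 reads each. On the log2(FPKM + 1) scale the limma fold change was -0.49 with an SE of 0.069 and a 95% confidence interval of -0.65 to -0.32. The difference exceeded the spread between replicates, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries can give. In the limma fit over all genes VASP, the targeted gene set in advance, ranked 3 by unadjusted p (0.00018). Its limma adjusted p was 0.579, so it did not pass the threshold. With library quality weights in limma its adjusted p was 0.0182. These weights were 4.24 for control siRNA replicate 2 and 0.122 and 0.819 for control siRNA replicates 1 and 3.

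**Figure D1:**
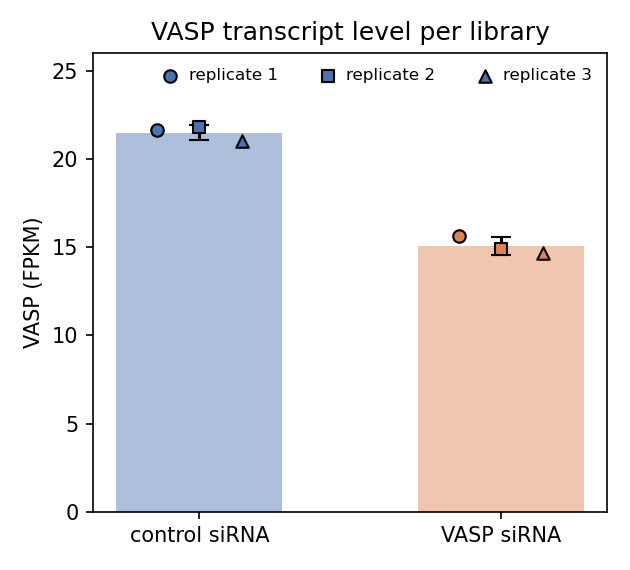
VASP level in FPKM in each library, with points for replicates 1 to 3 and bars for the group mean with SD (n = 3 per group). The control libraries lie between 21.02 and 21.8 FPKM and the VASP siRNA libraries between 14.7 and 15.6 FPKM.

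No gene passed an adjusted p of 0.05 in limma among the 11633 tested, 0 higher and 0 lower, and the smallest adjusted p was 0.579. At an unadjusted limma p under 0.05 there were 752 genes, 286 higher and 466 lower with VASP siRNA, where 581.6 are expected by chance. A split that mixed the groups, with control siRNA replicates 1 and 2 and VASP siRNA replicate 1 against the rest, gave 770. The groups did not overlap at 1695 genes (14.6%), where chance gives 10%. Library quality weights called 41 genes, 11 higher and 30 lower. There the control mean rested mostly on control siRNA replicate 2, with a weight of 4.24 against 0.122 and 0.819 for replicates 1 and 3. That library also stands apart, as given below.

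The 10 genes with the smallest unadjusted limma p are given as values only, since none passed the threshold. Besides VASP they held 7 with lower levels under VASP siRNA. COTL1, which encodes the filament-binding coactosin-like protein, had 11.05 ± 1.01 FPKM with control siRNA and 6.78 ± 0.43 FPKM with VASP siRNA. C1QBP, whose product resides mainly in mitochondria, had 57.8 ± 3.83 against 38.8 ± 1.56 FPKM. GAL, the precursor of the neuropeptide galanin, had 25.8 ± 2.81 against 16.8 ± 0.55 FPKM, and EPDR1 had 2.95 ± 0.083 against 1.59 ± 0.12 FPKM. Among non-coding genes, SNHG19 had 15.8 ± 2.41 against 8.68 ± 0.65 FPKM. SNORD6, a small nucleolar RNA, had 14.98 ± 1.33 against 8.89 ± 0.49 FPKM and the antisense RNA BX293535.1 had 3.21 ± 0.51 against 1.60 ± 0.063 FPKM. The last pair rested on 10 to 19 and 7 to 16 reads per library. The 2 genes with higher levels were A2M, a secreted protease inhibitor, at 19.3 ± 3.84 against 35.0 ± 2.67 FPKM, and TSC22D3, a glucocorticoid-induced gene, at 25.7 ± 0.26 against 35.2 ± 1.56 FPKM (SD, n = 3 throughout). SNORD6 lies within TAF1D, SNHG19 spans SNORD60, and C1QBP and EPDR1 overlap other genes on their own strand, so their reads could be shared with these. COTL1, TSC22D3, A2M and EVL overlap genes on the other strand, as C1QBP and EPDR1 do as well. The strand setting is not given, so reads could be shared there too. The VASP paralogs ENAH and EVL had log2 fold changes of 0.15 and 0.13 with SEs of 0.12 and 0.10, and adjusted limma p of 0.768 for each.

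Of 31 fixed gene lists tested with limma's camera at a preset correlation of 0.01, 12 were called at an adjusted p under 0.05, 6 higher and 6 lower in VASP siRNA, although no member of any list passed the threshold over all genes. None of the 12 calls held with an estimated correlation, nor in fry. Adjusted over the list alone, 3 members passed: COTL1 of the actin list, FHL1 of the SRF list and LUM of the fibroblast list. Members named below as examples were chosen after their values were seen, and none passed over all genes. They come from the members with the smallest p among those that go in their list's direction. A member with a smaller p could go the other way. In the cholesterol list, for instance, 0 members were higher and 1 lower at an unadjusted limma p under 0.05.

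The 6 lists that were lower covered ribosomal proteins, oxidative phosphorylation, heat shock, NRF2 and NF-kB targets and, as a sign of RNA quality, mitochondrially encoded genes. Of 75 cytosolic ribosomal protein genes, 73 had negative fold changes, with a mean log2 fold change of -0.25 (camera adjusted p = 2.93e-13, and adjusted p = 0.51 with an estimated correlation). RPS2 was at 752.6 ± 89.4 against 572 ± 37.4 FPKM and RPL28 at 52.7 ± 7.83 against 41.4 ± 2.09 FPKM (SD, n = 3). Of 46 nuclear-encoded oxidative phosphorylation genes, 44 were negative, with a mean of -0.18 (camera adjusted p = 9.68e-07, and adjusted p = 0.51 with an estimated correlation). ATP5G1, a subunit of ATP synthase, was at 26.4 ± 5.15 against 17.8 ± 1.06 FPKM. All 18 cytosolic heat shock genes were negative, with a mean of -0.26 (camera adjusted p = 1.44e-07, and adjusted p = 0.46 with an estimated correlation), among them the chaperone HSPA8 at 203 ± 47.6 against 150 ± 14.7 FPKM and HSPH1 at 15.9 ± 0.58 against 13.2 ± 0.65 FPKM. Of 12 mitochondrially encoded genes, 11 were negative, with a mean of -0.17 (camera adjusted p = 0.0028, and adjusted p = 0.46 with an estimated correlation). Of 20 NRF2 targets, 16 were negative, with a mean of -0.19 (camera adjusted p = 0.0028, and adjusted p = 0.46 with an estimated correlation), including the ferritin light chain FTL at 1411 ± 483 against 780 ± 24.1 FPKM. Of 15 NF-kB and TNF targets, 13 were negative, with a mean of -0.16 (camera adjusted p = 0.020, and adjusted p = 0.46 with an estimated correlation). Without control siRNA replicate 1 the ribosomal mean was -0.071 and the oxidative phosphorylation mean -0.037, and both calls ended (camera adjusted p = 0.103 and 0.665), while the heat shock call held at a mean of -0.17. In control siRNA replicate 1 the ribosomal genes lay 0.49 above their mean over the 6 libraries, against 0.031 or less in each other library. Histone genes listed as lacking poly(A), fixed as a sign of RNA quality, lay 0.47 above their mean there, against -0.25 to 0.15 in each other library. Whether each of these genes lacks poly(A) was not tested. Mitochondrially encoded genes lay at -0.016. The NF-kB call ended with means as large without control siRNA replicate 1 (-0.17, camera adjusted p = 0.103) or VASP siRNA replicate 1 (-0.16, 0.0879), and with a smaller mean without control siRNA replicate 2 (-0.062, 0.249). It ended as well at a mean of at least 5 FPKM (-0.11, 0.142). The NRF2 list lay 0.22 above its mean over the 6 libraries in control siRNA replicate 2, against 0.040 and 0.021 in the other control libraries, and AKR1B10 had 333 reads there against 11 to 19 in each other library. The NRF2 call held without control siRNA replicate 2 (mean -0.13, camera adjusted p = 0.0153). Leaving out control siRNA replicates 1 and 2 together leaves a lone control library, so only means are given for that setting. They were -0.11 for NRF2 targets, -0.16 for heat shock and -0.22 for mitochondrially encoded genes. For ribosomal proteins, oxidative phosphorylation and NF-kB targets they were 0.0055, -0.0075 and 0.0062. The mitochondrially encoded list turned to a mean of 0.017 under quantile normalization (camera adjusted p = 0.964), and its call ended with no filter on low values (-0.16, 0.434) and with length trends removed (-0.11, 0.0962).

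The 6 lists that were higher covered hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis, mitosis, TGF-beta targets and fibroblast markers. Of 35 hypoxia and glycolysis genes, 28 had positive fold changes, with a mean of 0.084 (camera adjusted p = 0.0012, and adjusted p = 0.46 with an estimated correlation). HK2, a hexokinase, was at 36.4 ± 3.26 against 44.7 ± 2.57 FPKM and ENO2, an enolase, at 39.8 ± 0.78 against 46.7 ± 2.40 FPKM (SD, n = 3). Of 23 cholesterol synthesis genes, 20 were positive, with a mean of 0.10 (camera adjusted p = 0.012, and adjusted p = 0.46 with an estimated correlation), and HMGCR, the rate-limiting enzyme, was at 13.2 ± 1.92 against 15.8 ± 0.80 FPKM. Of 18 fatty acid synthesis genes, 13 were positive, with a mean of 0.13 (camera adjusted p = 0.0497, and adjusted p = 0.61 with an estimated correlation), and SCD was at 382 ± 64.8 against 508 ± 33.0 FPKM. Of 47 mitosis genes, 30 were positive, with a mean of 0.057 (camera adjusted p = 0.031, and adjusted p = 0.46 with an estimated correlation), and TOP2A was at 213 ± 18.7 against 251 ± 9.81 FPKM. Of 22 TGF-beta targets, 17 were positive, with a mean of 0.085 (camera adjusted p = 0.017, and adjusted p = 0.46 with an estimated correlation). All 7 tested fibroblast markers were positive, with a mean of 0.22 (camera adjusted p = 0.012, and adjusted p = 0.46 with an estimated correlation). Of the 15 markers on that list 5 also stand on another list, and LUM was at 47.0 ± 4.76 against 60.8 ± 2.82 FPKM. Without control siRNA replicate 1 the fatty acid mean was 0.021 and its call ended (camera adjusted p = 0.255). The calls of the fibroblast, TGF-beta, cholesterol and hypoxia lists held there, with means of 0.11, 0.039, 0.065 and 0.13. With control siRNA replicate 2 left out as well, which leaves a lone control library, these means were 0.065, 0.090, 0.041 and 0.14. The fibroblast call ended with no filter on low values (mean 0.090, camera adjusted p = 0.0758). Without control siRNA replicate 2 the calls of hypoxia (mean 0.065, camera adjusted p = 0.131), cholesterol (0.11, 0.0943), fatty acid (0.17, 0.0943) and mitosis genes (0.060, 0.288) ended. Without control siRNA replicate 3 those of hypoxia (mean 0.058, camera adjusted p = 0.0750), mitosis (0.073, 0.0695) and TGF-beta genes (0.082, 0.0708) ended. Without VASP siRNA replicate 2 or 3 the fatty acid call (mean 0.13, camera adjusted p of 0.0750 and 0.0724) and the mitosis call (0.053 and 0.055, 0.0656 and 0.0772) ended with means close to those of all 6 libraries. The fatty acid call also ended with pseudocounts of 0.1 and 0.5 (camera adjusted p = 0.0516 and 0.0507), rescaling to equal sums (0.0573), no variance trend (0.0532) and length trends removed (0.0697). The mitosis and TGF-beta calls ended under median-of-ratios scaling (means 0.037 and 0.066, camera adjusted p = 0.134 and 0.0528), and the mitosis call in limma-voom on recovered reads (0.058, 0.0503).

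**Figure D2:**
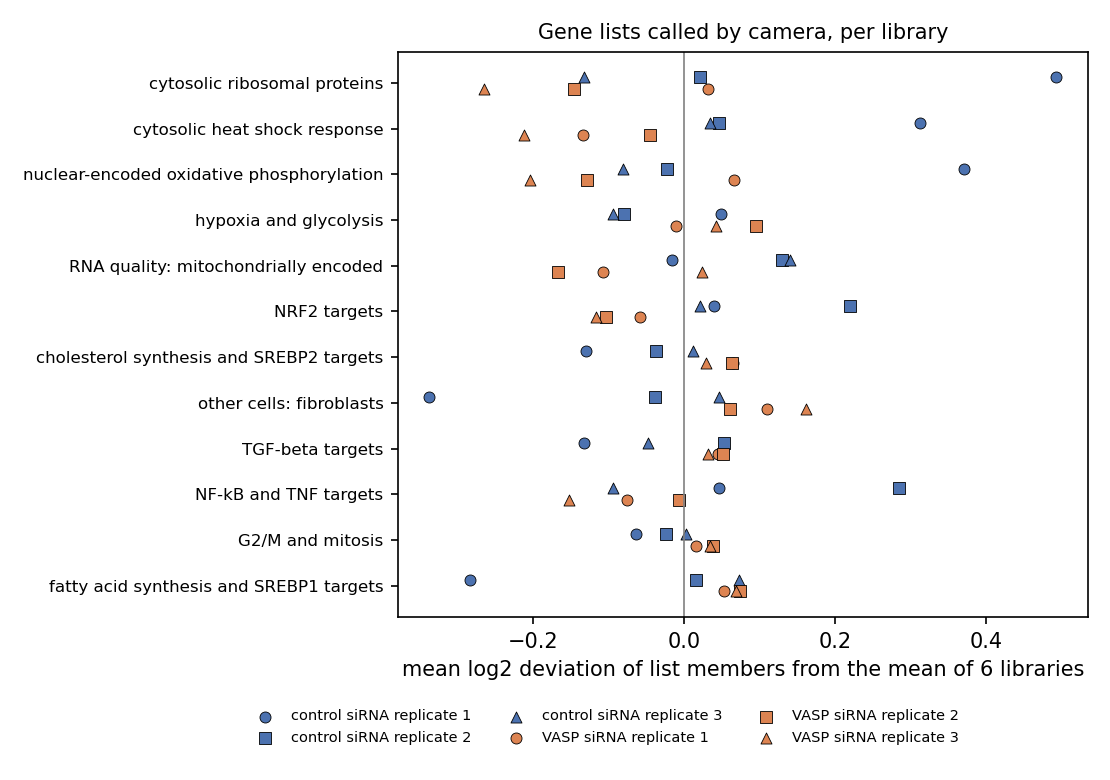
Mean log2 deviation of the members of each of the 12 called lists from their mean over the 6 libraries, with 1 point per library. Control siRNA replicate 1 lies apart in the ribosomal list at 0.49 and in the fibroblast list at -0.34.

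Lists on actin and adhesion, the known field of VASP, were not called with all 6 libraries and the settings fixed for the comparison, though some alternatives called them. The actin filament list had a mean log2 fold change of -0.055 over 49 genes (camera adjusted p = 0.0913), with CFL1, or cofilin, at 69.4 ± 5.28 against 56.7 ± 1.63 FPKM (SD, n = 3). The SRF and MRTF target list had a mean of 0.11 over 19 genes (camera adjusted p = 0.0867), with FHL1 at 38.6 ± 1.22 against 51.1 ± 1.73 FPKM. The Ena/VASP family and partner list had a mean of 0.058 over 20 genes (camera adjusted p = 0.297), and the integrin and focal adhesion list 0.042 over 30 genes (camera adjusted p = 0.739). Without control siRNA replicate 1 the means of the last pair turned to -0.033 and -0.056, and under rescaling to equal sums that of the actin list turned to 0.011. Camera compares a list with the other genes. The rescaling moved the median log2 fold change over all genes from 0.015 to 0.072, so the actin mean stayed below it (camera adjusted p = 0.131). The SRF and MRTF list was called under quantile normalization (camera adjusted p = 0.0174), a replicate block (0.0178), a mean of at least 5 FPKM (0.0361), rescaling to equal sums (0.0414), and without VASP siRNA replicate 2 (0.0393) or 3 (0.0431). The actin list was called without control siRNA replicate 2 (camera adjusted p = 0.0365) or VASP siRNA replicate 3 (0.0499) and with length trends removed (0.0496), and the Ena/VASP list without control siRNA replicate 3 (0.0358). With an estimated correlation and all 6 libraries the camera adjusted p was 0.46 for the SRF and actin lists and 0.84 for the Ena/VASP list. Epithelial junction genes (adjusted p = 0.295), mesenchymal genes (0.747), YAP and TAZ targets (0.960) and Wnt targets (0.801) also missed the threshold in camera. So did estrogen response (0.739), luminal identity (0.801), E2F (0.509), p53 (0.966), apoptosis (0.317), interferon-stimulated (0.0867), unfolded protein response (0.242), autophagy (0.330), small RNA silencing (0.242), histone (0.137) and basal breast (0.0867) lists. Of these the interferon-stimulated list was called in 4 alternatives, with means of -0.26 to -0.10 (camera adjusted p of 0.0273 to 0.0449), and the basal breast list in 4 that leave out a single library, with means of -0.15 to -0.12 (0.0329 to 0.0449). The histone list was called in 3 such alternatives, with means of -0.28 to -0.25 (camera adjusted p of 0.00334 to 0.0362), and the autophagy list with library quality weights (0.034, 0.0448). With an estimated correlation and all 6 libraries the camera adjusted p was 0.46 for the interferon-stimulated, 0.58 for the basal breast, 0.77 for the histone and 0.51 for the autophagy list. The mean, median or test of the luminal, Wnt, YAP and TAZ, and p53 lists differed in sign. Leukocyte and endothelium lists had fewer than 5 tested members. All 11 listed leukocyte markers had means under 1 FPKM, and so did 7 of 10 endothelium markers.

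Of 19 listed luminal identity genes, 9 had a mean of at least 10 FPKM, 3 lay between 1 and 10 FPKM and 7 were under 1 FPKM. Several luminal breast genes, on that list or not, that the cell line label would lead to look for were near 0 in all 6 libraries. ESR1, the estrogen receptor, had at most 15 reads and 0.068 FPKM in any library, and PGR, the progesterone receptor, at most 2 reads. CDH1, or E-cadherin, reached at most 0.04 FPKM. GATA3 ranged from 0.55 to 1.197 FPKM and FOXA1 from 2.23 to 2.93 FPKM. The keratins KRT8 and KRT18 were at 148 to 180 and 89.0 to 113 FPKM, and the basal keratin KRT17 at 220 to 298 FPKM. KRT5, on the basal breast list as well, had at most 3 reads in any library. Of 15 listed basal breast genes, 8 had a mean of at least 10 FPKM, 3 lay between 1 and 10 FPKM and 4 were under 1 FPKM. Of 27 listed mesenchymal genes, 16 had a mean of at least 10 FPKM, 6 lay between 1 and 10 FPKM and 5 were under 1 FPKM. VIM was at 88.5 to 124 FPKM, SPARC at 162 to 186 FPKM, CAV1 at 50.5 to 66.6 FPKM and COL5A1 at 123 to 214 FPKM. CDKN2A was at 33.3 to 50.5 FPKM and MTAP at 2.62 to 3.63 FPKM, a pair picked after the values were seen.

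**Figure D3:**
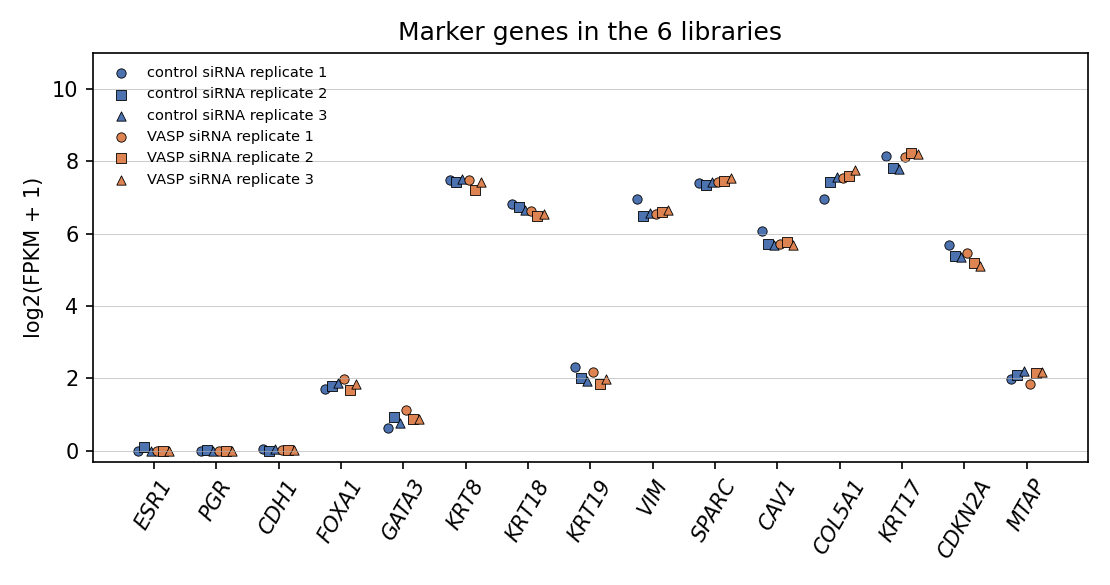
Level of 15 marker genes as log2(FPKM + 1) in each library, with 1 point per library, colours for the groups and shapes for the replicates. ESR1, PGR and CDH1 lie near 0 in all 6 libraries, while VIM lies between 88.5 and 124 FPKM.

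2 control libraries stood apart. The first principal component held 50.6% of the variance and placed control siRNA replicate 1 at -35.5 and the others at 4.38 to 9.46. The SD of its log2 deviations from the median of the others was 0.391, against 0.199 to 0.230 for the rest. Control siRNA replicate 2 showed 2897 genes above 0 that no other library showed, against 389 to 761 in each other library. Control siRNA replicate 3 shared higher reads with it at some genes, chosen after their values were seen. CCND1 had 639 and 260 reads in control siRNA replicates 2 and 3, against 77 to 88 elsewhere, and SPP1 109 and 73, against 12 to 17. At CXCL5 and ALDH1A1, with 697 and 301 reads in control siRNA replicate 2, control siRNA replicate 3 had 0 and 1. Without control siRNA replicate 1, 8 lists were called, all among the 12, and no gene passed the threshold. Leaving out control siRNA replicates 1 and 2 together leaves a lone control library, so only means are given. Hypoxia, TGF-beta, NRF2, heat shock and mitochondrially encoded genes then had means of 0.14, 0.090, -0.11, -0.16 and -0.22. The rest of the 12 lists had means of -0.0080 to 0.065.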

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

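All alternatives were set before the data were examined except 4 chosen after seeing them: control replicates 1 and 2 left out together, length trends removed, limma-voom on recovered reads, and protein-coding genes only. VASP kept its direction under all 22 alternatives, with log2 fold changes of -0.51 to -0.42 and limma adjusted p of 0.0182 to 0.982. Library quality weights (0.122 for control replicate 1, 4.24 for control replicate 2) gave -0.51, past the threshold, and 41 genes; every other setting run, including adjusted p under 0.1, gave 0 genes. Fixed lists called ranged from 8 to 14 with a single library left out. Estimated correlation, fry and fry mixed each called 0 lists. Without control replicates 1 and 2 together, the lone control is assumed to vary like the rest, so only means are given. There the camera direction turned for integrins and focal adhesion (-0.095), ribosomal proteins (0.0055), NF-kB targets (0.0062) and oxidative phosphorylation (mean -0.0075). The fatty acid mean also changed sign (-0.0080), though its camera direction did not turn. The cause was not tested. Of 743 list values under alternatives, 659 stayed on their side of the threshold, where means of lists not called could change sign, 58 calls were lost and 22 gained in the same direction, and 4 turned. With the replicate number as a block, 0 genes and 13 lists were called and VASP was at -0.49; same-number correlations of 0.158, 0.095 and 0.216 do not show pairing, though all 6 libraries correlate best with their own number, a hint from the data. Low depth limits SNORD6 and BX293535.1, at 7 to 19 reads.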

Other observations

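The tests of marker genes, of depth and of extra genes in control siRNA replicates 1 and 2 were chosen after the results were seen, while the length trend, the lincRNA comparison, the splits of the libraries and the 3' UTR scan were set before.

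ESR1, PGR, CDH1 and other luminal breast genes were near 0 in cells labelled MCF-7, with 7 of 19 listed luminal identity genes under 1 FPKM and 9 at 10 FPKM or more, KRT8 and KRT18 among the latter. A mixture with a minority of other cells is argued against, since ESR1 and CDH1 reached at most 0.068 FPKM in any library. MCF-7 cells that had switched off luminal genes are argued against by CDKN2A and MTAP, known to be deleted in MCF-7, whose lowest level was 2.62 FPKM. In all 6 libraries CDKN2A, with 2511 to 3540 reads, and MTAP, with 619 to 893, argue against RNA from cells that lack these genes alone. That covers MCF-7 with the known deletion. Another cell line under the MCF-7 label stays open, and which line it would be was not tested. The 4 conditions that all 6 libraries meet were written from these values, so meeting them is no separate test. No biological explanation from the design was tested, since both groups carry the same label.

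Control siRNA replicate 1 stood apart. Sequencing depth is argued against, as its 16206096 fragments lie inside the range of the others. A trend with transcript length was present. The Spearman correlation of its deviations with exonic length was -0.384, so shorter genes lay higher there, against -0.125 to 0.26 in the other libraries. Such a trend is argued against as the whole cause. The SD of its deviations stayed at 0.350 once such trends were removed, against 0.222 for the highest other library. RNA from other cells with genes of their own is argued against, as 0 genes had at least 20 reads in it and at most 3 in each other library, against 66 in control siRNA replicate 2. RNA from cells that express the same genes was not tested and stays open, as basal breast genes lay 0.21 above and fibroblast genes 0.34 below their mean there. A difference in handling or RNA quality stays open. Of the lists fixed as signs of RNA quality, histone genes listed as lacking poly(A) lay 0.47 above their mean there and mitochondrially encoded genes at -0.016. No test was set on these.

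Control siRNA replicate 2 held 66 genes with at least 20 reads and at most 3 in each other library, against 4 in the highest other library, led by CXCL5 with 697 reads and ALDH1A1 with 301. Genomic DNA is argued against for these 66 genes, where an even spread of reads over exonic length gives 1.8. RNA from other cells cannot be told apart from an induced response (66 genes). NF-kB targets and interferon-stimulated genes were also highest there, at 0.28 and 0.24 above their mean, which either explanation could give. Of the 66, CXCL1 with 40 reads stands on the NF-kB list and OAS2 with 30 on the interferon list. Others stand on neither list, such as CPLX2 with 240 reads and HNF1B with 30. For genes under 20 reads, genomic DNA may contribute, as reads per kb of protein-coding genes were 1.19 times those of lincRNA genes, though control siRNA replicate 3 gave 1.56 and the others 0.42 to 0.79. No biological explanation was tested.

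The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 0 genes, as did the highest other, so all 10 gave as many, and it gave 12 lists against 9 for the highest other, so 1 split gave as many. At an unadjusted limma p under 0.05 it gave 752 genes, against 770 for the highest other. Seed matches of the VASP siRNA, whose sequence is not given here, were looked for as 7-base sites in the 3' UTRs of 9799 genes. The lowest z for a site was -4.58 in the real split, and 5 of the 9 other splits gave as low a value, down to -5.24.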
